A study of Rattus norvegicus with 6 samples.

How the data were processed

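Circular RNAs (circRNAs), covalently closed transcripts formed by back-splicing, were measured in rat vascular smooth muscle cells on 6 single-colour (Cy3) microarrays, 3 from control cells and 3 from cells given platelet-derived growth factor BB (PDGF-BB). Per the labels, cells were kept in DMEM with 10% fetal bovine serum at 37 °C and 5% CO2, PDGF-BB was given at 20 ng/ml for 24 h, total RNA was extracted with Trizol, and labelled cRNA was made with random primers. Groups and replicate numbers were taken from the sample labels.

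Per the file headers, the authors' scanner files hold spot intensity from Agilent Feature Extraction version 11.0.1.1, and the processed intensity is background-subtracted within each array and not scaled between arrays. The submitters' processing notes name Agilent Feature Extraction and limma, with no order of steps. The authors also deposited a table of log2 values for 14145 circRNA probes. Its column medians were 5.73, 5.75 and 5.75 for controls 1, 2 and 3 and 5.73 for each PDGF-BB array, and each column correlated at 0.999 or above with the quantile-normalized log2 median spot signal of its array across probes. The values are thus log2, not centred per probe and run in the direction of spot brightness. With the processed signal, which is background-subtracted, the columns correlated less, at 0.9406 to 0.9584. This argues against a subtraction of that kind, and whether another background step was applied stays unknown.

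For the main results, the log2 of the processed signal was reduced by each array's 75th percentile over all non-control probes. Spots of one probe were averaged, and control spots and outlier-flagged spots were left out. Of 14145 circRNA probes, 12341 were well above background on at least 3 of the 6 arrays and 12313 of these had an unflagged value in both groups and were tested. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) without a replicate block, with Benjamini-Hochberg adjustment over the tested circRNA probes and a threshold of 0.05. The study's own threshold, a fold change of at least 1.5 with unadjusted p under 0.05, was applied to the same fit. Tests, main settings, gene lists and the rule for naming probes were set before the data were examined. A first run also required at least 2 unflagged arrays per group, which the plan did not. It was kept as an alternative and called the same 2 circRNA probes. The rule took up to 12 probes per direction: first those past the adjusted threshold with groups that did not overlap, by size, then those past the study's threshold without overlap, by p-value. It also took the 5 probes with the highest control mean.

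The files used here do not pair circRNA probes with host genes, so at most 2 probe IDs per direction are printed and the rest are summarised. For the same reason the 14 gene lists by host gene, the comparison of circRNAs from one host gene and the comparison of circRNA classes were not run. The arrays also carry 82 other non-control probes, here called linear transcript probes, with 10 to 20 spots each. Of these, 62 carry a transcript accession, and 39 accessions matched a gene symbol in the RefSeq table of assembly GRCr8 after versions were removed. Testing 47 of these probes (28 with a symbol, for 27 genes) as a separate family was chosen after seeing the data, as was naming the genes whose groups did not overlap and the reference genes, with every tested probe of each. None of the genes named this way belongs to any of the 14 lists.

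The procedure was tested on simulated data with the levels and spread of the 12313 probes of this comparison, with 200 probes changed in each of 20 runs. The adjusted threshold recovered 4.4% of probes changed 1.5-fold, 52.3% of those changed 2-fold and 98.1% of those changed 4-fold. In these runs an average of 7.95 unchanged probes also passed the adjusted threshold, and 252 passed the study's. With nothing changed, an average of 250 probes passed the study's threshold and 0.15 passed the adjusted one. The simulated noise was independent between probes, with no shift shared by an array. The planted 4-fold changes also ease the adjusted threshold for the smaller ones. These shares and counts may thus not hold in the real data.

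Alternatives covered background correction by normexp (offset 50), quantile and median scaling, the percentile over probes detected on all arrays, the detection filter, the replicate number as a block, each array left out, the authors' processed values, eBayes with trend and robust options, array weights and an unmoderated per-probe test. Normexp used the median spot signal in place of the mean signal that had been planned. Its offset of 50 is added to every signal, and the median processed circRNA signal per array ran from 23.1 to 45.4. Smaller log2 fold changes at dim probes thus follow in part from the setting itself. All 6 arrays share 1 scan time, so slide could not be a block. Spot coordinates place control 1 and the 3 PDGF-BB arrays in one column of the slide and controls 2 and 3 in the other; this column as a block, the 4 arrays of the first column alone, the negative control signal as a covariate and handling of outlier-flagged spots were added after seeing the data. Both column fits have control 1 as their only control against the 3 PDGF-BB arrays, so they rest on that array. Figures were drawn with matplotlib 3.10.9.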

Results

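The arrays addressed which circRNAs differ when rat vascular smooth muscle cells, the contractile cells of the vessel wall, are given PDGF-BB, a growth factor that drives them to divide and migrate. Of 14145 circRNA probes, 12478, 11696 and 12345 were well above background in controls 1, 2 and 3, and 12520, 12368 and 11588 in PDGF-BB arrays 1, 2 and 3. The group means were 12173 ± 418 for control and 12159 ± 500 for PDGF-BB (SD, n = 3 each; exact two-sided permutation test, p = 1, where the smallest p that 3 against 3 allows is 0.1). On all 6 arrays 11218 probes (79.3%) were well above background. No non-control spot was saturated. The labels do not say whether the samples were separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

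PDGF-BB cells differed from control cells at 2 circRNA probes after adjustment, 1 higher and 1 lower. ASCRPR002114 rose 3.63-fold, from -2.16 ± 0.21 in control to -0.30 ± 0.16 in PDGF-BB (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3 each), a log2 fold change of 1.86 (SE 0.19, limma adjusted p = 0.0334). ASCRPR012587 was 4.56-fold lower, at 0.22 ± 0.38 in control and -1.97 ± 0.18 in PDGF-BB, a log2 fold change of -2.19 (SE 0.23, limma adjusted p = 0.0334). For both probes, all 3 PDGF-BB arrays lay on one side of all 3 controls, and all 6 arrays were well above background. The files do not pair these probes with genes.

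The next probe in each direction did not pass the adjusted threshold. ASCRPR011149 had a log2 fold change of 1.42 (SE 0.21, limma adjusted p = 0.142), with means of -0.34 ± 0.29 in control and 1.08 ± 0.22 in PDGF-BB. It passed with normexp background correction (log2 fold change 1.01, adjusted p = 0.00499), from the authors' processed values (1.22, adjusted p = 0.0459) and with an intensity trend and robust eBayes (adjusted p = 0.0445). With 1 array left out its limma adjusted p ran from 0.184 to 0.482. ASCRPR006124 had a log2 fold change of -1.87 (SE 0.25, limma adjusted p = 0.142) and was well above background on all 3 control arrays but only 1 PDGF-BB array, so its PDGF-BB level is near background; its log2 fold change was -0.22 with normexp and -0.48 from the authors' processed values. The 12 probes named as higher spanned fitted folds of 2.05 to 3.63 and the 12 named as lower 2.06 to 4.56, and 1 of each set was not well above background on any array of its dimmer group. Among the 5 probes with the highest control signal, log2 fold changes ran from 0.044 to 0.52 and none passed (lowest limma adjusted p = 0.57).

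**Figure D1:**
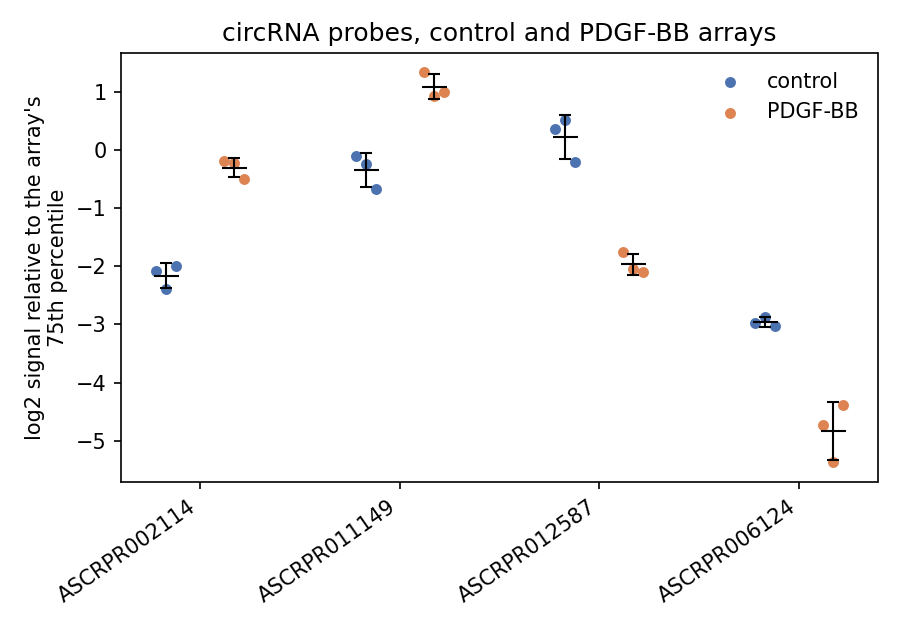
Log2 signal relative to the array's 75th percentile (vertical axis) for 4 circRNA probes (horizontal axis). Points are arrays, black bars are mean ± SD of 3 arrays, and in each probe the PDGF-BB arrays do not overlap the controls; in the main setting only ASCRPR002114 and ASCRPR012587 passed the adjusted threshold.

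The calls and sizes at ASCRPR002114 and ASCRPR012587 depended on the setting. The log2 fold changes were 0.82 and -1.06 with normexp and 1.25 and -1.59 from the authors' processed values, and both probes passed there. With the array column as a block the log2 fold changes were 1.78 and -2.32 (limma adjusted p = 0.424 and 0.284), and among the 4 arrays of that column alone 1.78 and -2.32 (adjusted p = 0.432 and 0.167); over all settings the adjusted p ran from 0.00224 to 0.432. Another circRNA probe passed in each of those 2 column fits, and with normexp 56 probes passed, 42 higher and 14 lower. Neither named probe passed with the replicate block, no detection filter, the unmoderated per-probe test or the negative control signal as a covariate. With any 1 array left out neither named probe passed, and the only call was 1 other probe, without control 1.

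At the study's own threshold 594 circRNA probes differed, 305 higher and 289 lower in PDGF-BB cells. At unadjusted p under 0.05 there were 1111 probes, where chance gives 616 and the other splits of the 6 arrays into 3 and 3 gave 112 to 1911. At the study's threshold those splits gave 73 to 1050. Simulated data with nothing changed, where noise is independent between probes, put 250 past it. The groups did not overlap at 1932 probes (15.7%), where chance gives 10%. At a fold change of at least 2, 95 probes remained past the threshold. Without control 1 the count at the study's threshold was 1157. With normexp it was 215, with 178 higher and 37 lower, and from the authors' processed values 141, with 49 higher and 92 lower.

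Among linear transcript probes, a family added after seeing the data, 0 of 47 passed the adjusted threshold in limma and 6 had an unadjusted p under 0.05, all with higher signal in PDGF-BB cells. Fgf2, which encodes basic fibroblast growth factor, a mitogen for smooth muscle, had a log2 fold change of 1.01 (SE 0.25, limma adjusted p = 0.245), with means of -4.28 ± 0.40 in control and -3.27 ± 0.24 in PDGF-BB. The Fgf2 probe was well above background on 2 of 3 controls and all 3 PDGF-BB arrays. With normexp, whose offset reduces log2 fold changes at dim probes, it had a log2 fold change of 0.12. Gdnf, encoding glial cell line-derived neurotrophic factor, had a log2 fold change of 0.74 (SE 0.26, limma adjusted p = 0.319), which was 0.47 without PDGF-BB 1 and 0.32 with normexp. Sdha, a subunit of mitochondrial succinate dehydrogenase and one of the reference genes, had a log2 fold change of 0.42 (SE 0.17, limma adjusted p = 0.326). With the array column as a block it was 0.235. For Ndfip1, an adaptor of Nedd4-family ubiquitin ligases, the log2 fold change was 0.33 (limma adjusted p = 0.504) and with normexp 0.18. In Fgf2, Gdnf, Sdha and Ndfip1 all 3 PDGF-BB arrays lay above all 3 controls, but genes were picked for such a split, so it adds no support. Ndfip1 was not among the 6 probes above (limma unadjusted p = 0.112). The groups did not overlap at 11 of the 47 linear probes (23.4%), where chance gives 10%. Of the 28 probes with a gene symbol, 23 had a positive and 5 a negative log2 fold change. With 1 array left out 17 to 26 were positive and 2 to 11 negative. In the column fits, where control 1 is the only control, 12 were positive and 16 negative.

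The reference gene probes, Sdha among them, did not pass the adjusted threshold. The Sdha change of 0.42 was the largest of this set. Actb, cytoskeletal beta-actin, had a log2 fold change of -0.17 (SE 0.15, limma adjusted p = 0.753), with all 3 PDGF-BB arrays below the controls. Hsp90ab1, a cytosolic chaperone, was at 0.40 (adjusted p = 0.504) and B2m, the light chain of MHC class I, at 0.26 (adjusted p = 0.753). With the array column as a block they were at 0.046 and 0.090; with quantile normalization Hsp90ab1 was at 0.047 and Actb at -0.31, and B2m was at 0.076 without control 3 and 0.17 without PDGF-BB 1. The glycolytic genes Pgk1 and Ldha were at 0.13 and 0.0098, the ribosomal protein genes Rplp1 and Rpl13a at 0.080 and -0.047, and the lysosomal enzyme gene Gusb at 0.011, with limma adjusted p from 0.923 to 0.976. Another Ldha probe, from the array's catalogue set, was at 0.29 (limma adjusted p = 0.812). Its control mean was 4.79, against -0.72 for the Ldha reference probe, so both may not report the transcript alike. The probes for these last 5 genes each changed sign in at least 1 other setting. With the array column as a block the Fgf2 log2 fold change was 0.61.

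**Figure D2:**
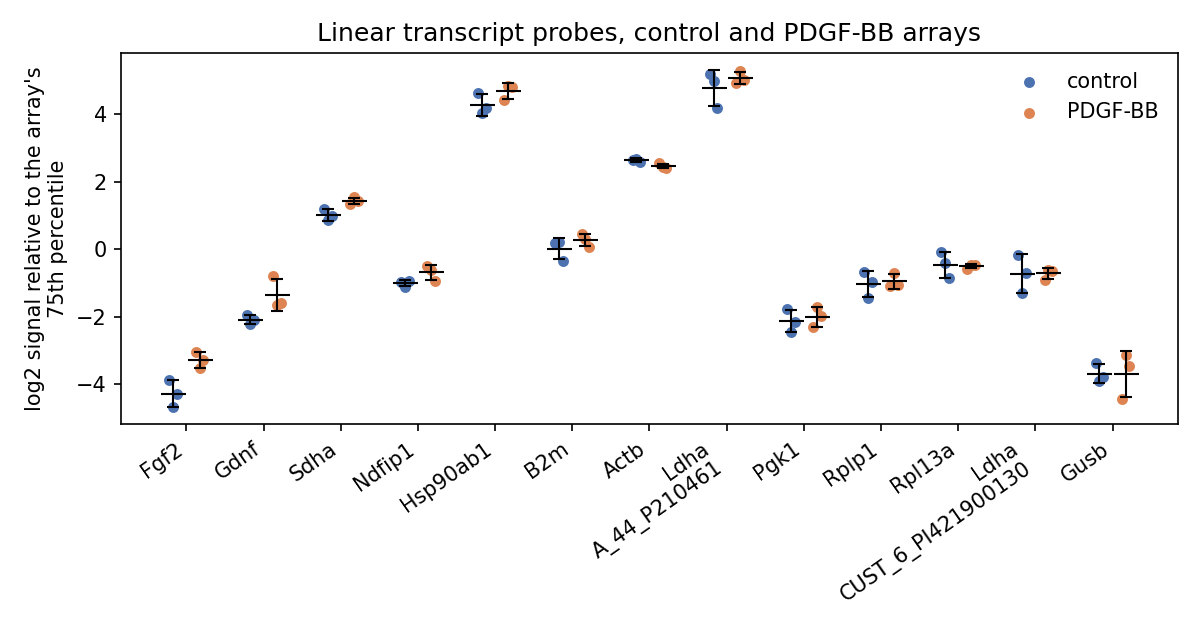
Log2 signal relative to the array's 75th percentile (vertical axis) for 13 linear transcript probes (horizontal axis), with points for arrays and black bars for mean ± SD of 3 arrays. Fgf2, Gdnf, Sdha and Ndfip1 lie higher in all PDGF-BB arrays than in the controls and Actb lower, and none passed the adjusted threshold. Genes were picked for groups that did not overlap or as reference genes.

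Across circRNA probes, the first and second principal components (39.3% and 22.3% of variance) did not part the groups, and component 3 (19.8%) did, with controls from -22.7 to -0.544 and PDGF-BB arrays from 6.6 to 25.5; by chance a given component parts 3 from 3 in 10% of cases. Mean correlation was 0.971 among controls, 0.981 among PDGF-BB arrays and 0.973 between groups. Control 1 correlated at 0.983 with PDGF-BB 2 and 0.980 with PDGF-BB 3, against 0.970 and 0.969 with controls 2 and 3. Probes are not independent replicates.

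**Figure D3:**
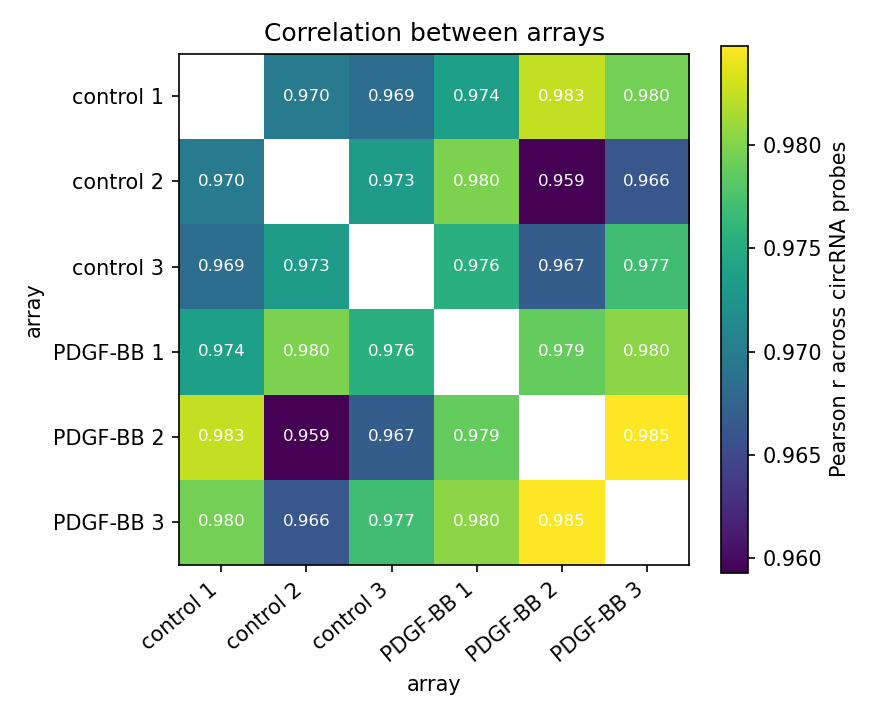
Pearson correlation between each pair of arrays across circRNA probes (colour scale), with arrays on both axes and the diagonal left blank. Control 1 has its highest values with PDGF-BB 2 (0.983) and PDGF-BB 3 (0.980).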

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

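The column, covariate, spot-handling, linear-probe and one-group detection settings, and leaving out arrays for detected probes, were chosen after seeing the data. The count of 2 circRNA probes past the adjusted threshold stayed within 1.5 times under 10 settings. It was 56 with normexp (42 higher, 14 lower) and 4 with the authors' processed values. With no detection filter, the replicate block, the unmoderated per-probe test or the negative control signal as a covariate it was 0. Leaving out 1 array gave 0 to 1. The cause was not tested. ASCRPR002114 and ASCRPR012587 kept their direction in all settings run; each was called in 11 of them and not in the other 12, among these every fit with 1 array left out. Their log2 fold changes were 0.82 and -1.06 with normexp and 1.25 and -1.59 from the authors' processed values. Where the call was lost, the size stayed close to the main one, at 1.86 and -2.19 with the replicate block and with no filter, and at 1.74 to 1.95 and -2.40 to -2.04 with 1 array left out.

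The count of 594 at the study's threshold became 215 with normexp (178 higher, 37 lower), 141 with the authors' processed values (49 higher, 92 lower) and 140 from them without a detection filter, 949 with array weights, 345 with the unmoderated test, 902 within the first column and 95 at a fold change of at least 2. Leaving out 1 array gave 500 to 1157, the highest without control 1. Regressed on the main log2 fold changes, those from the authors' values had a slope of 0.28 in the dimmest quartile of probes and 0.74 in the brightest.

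Same-numbered arrays had deviations from their group mean that correlated at -0.45, -0.37 and 0.21. Deviations in a group balance out, so these correlations depend on one another. They cannot show whether the replicate numbers pair the samples, and the labels do not say. Deviations of control 1 and PDGF-BB 2 correlated at 0.5, and those of control 2 and PDGF-BB 1 at 0.51. The other differently numbered pairs ran from -0.21 to -0.0013. What the arrays of the positive pairs share was not tested, and the main fit does not model it. With the replicate block 0 circRNA probes passed the adjusted threshold and 578 the study's, and 2 linear probes had an unadjusted p under 0.05.

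No linear probe passed the adjusted threshold in any setting run. Their count of 6 at unadjusted p became 2 to 9 with 1 array left out (3 without control 2, and 2 without control 3, PDGF-BB 1 or PDGF-BB 2). With the column as a block and within the first column the log2 fold change was -0.22 for Pgk1, -0.28 for Rplp1, -0.41 for Rpl13a, -0.55 and -0.12 for the reference and catalogue probes of Ldha and -0.31 for Gusb; the catalogue probe was -0.15 with quantile normalization. The values of Ldha that follow are of the reference probe unless named. Rpl13a was 0.041 with array weights. With normexp Ldha was -0.016. With the percentile over probes detected on all arrays Ldha was -0.015 and Gusb -0.013, with the negative control covariate -0.060 and -0.063, and with outlier-flagged spots kept -0.016 and -0.041. With 1 array left out the ranges were -0.035 to 0.30 for Pgk1, -0.13 to 0.26 for Rplp1, -0.25 to 0.14 for Rpl13a, -0.28 to 0.29 for Ldha, -0.010 to 0.49 for its catalogue probe and -0.26 to 0.39 for Gusb.

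The difference in detected probes per array, -14.33 (PDGF-BB minus control), was 48.7 by the flag for positive and significant signal, and -252.8 to 271 with 1 array left out. The count of 10 probes detected on every array of one group and none of the other was 16 by that flag and 19 to 57 with 1 array left out. Slide as a block and the settings for gene lists, host genes and circRNA classes were not run.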

Other observations

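Only the test of a wrong label on control 1 was fixed before its result was seen; the other tests here were chosen afterwards.

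The 2 circRNA probes past the adjusted threshold compare with at most 0 in the other splits of the 6 arrays into 3 and 3, and 1 of the 10 splits gave as many. At the study's threshold the real count of 594 was exceeded by 1050 in the split of control 1, PDGF-BB 2 and PDGF-BB 3 against the rest, which is the real split with the labels of control 1 and PDGF-BB 1 exchanged, so 2 of 10 splits gave as many; that split also gave 1911 probes at unadjusted p under 0.05, against 1111 in the real one. For linear probes, any split gives at least the real 0 calls (10 of 10, highest other 1), so that count tests nothing. At unadjusted p under 0.05, 3 of 10 splits gave at least the 6 linear probes (highest other 10). Detection on all arrays of one group and none of the other held at 10 circRNA probes, 6 in PDGF-BB and 4 in control, against up to 62 in other splits, and 7 of 10 gave as many. With 10 splits a share under 0.05 cannot be reached.

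Control 1 resembled the PDGF-BB arrays more than the other controls, by 0.00937 in mean correlation (95% interval over resampled probes 0.00856 to 0.0102). Control 3 did so too, by 0.0022, though its mean with the other controls includes control 1. For control 2 the difference was -0.0032. The tests below concern control 1. Over the 2421 brightest probes the difference for control 1 was 0.0202 (0.0172 to 0.0237). This argues against background signal at dim probes as its only source. Correlations over a narrower range of levels are on another scale, so its size cannot be set against 0.00937. A swap with PDGF-BB 2 or 3 is also argued against: each correlated less with controls 2 and 3 than with its own group (differences -0.0187 and -0.011), and exchanging the labels lowered the count at the study's threshold to 108 and 383. A swap with PDGF-BB 1 stays open, since its difference was small (-0.00196, interval -0.00271 to -0.0012) and exchanging these labels is the split that gave 1050 probes. PDGF-BB 1 and control 2 (r = 0.980) share a slide row and had the highest negative control signals, 18.8 and 19.8 against 15.7 to 16.3. Control 3 and PDGF-BB 2 also share a row, with r = 0.967. Neither row nor negative control signal was tested as a source of this closeness. The array column cannot be told apart, because control 1 is the one control in its column (PDGF-BB 1 correlated less with it than with controls 2 and 3, difference -0.00396, but 1 array decides nothing), and a culture or RNA preparation that differed was not tested. Of the 1157 probes past the study's threshold without control 1, 1149 had a value on that array (its outlier spots were left out), and at 64.9% (62 to 67.6) of these it lay nearer the PDGF-BB mean, against 35% and 53.5% for controls 2 and 3 tested alike, so a wrong label may be an explanation and stays open as a hypothesis. Probes picked for a difference from the other controls can also place a rightly labelled control nearer the PDGF-BB mean. The resemblance was seen on the same arrays, so this share is no separate evidence for a wrong label. The intervals cover probes, not arrays.

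Fold changes of circRNA probes with consecutive numbers were almost unrelated (Pearson r = 0.021 across 10745 pairs, permutation p = 0.029 from 10000 permutations, 1 relation computed). The sign is the one that related neighbours would give, but probes are not independent replicates and the relation leaves nearly all variation unaccounted for.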
